A study of Homo sapiens with 11 samples.

How the data were processed

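RNA sequencing was carried out on human pulmonary microvascular endothelial cells, obtained from a commercial supplier and kept in 1% oxygen for 0, 8, 24 or 48 h. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with an Illumina TruSeq preparation. Per the submitters' processing notes, reads were aligned with BWA to the human genome build hg19. Versions, the counting tool, the gene annotation, the treatment of reads that map to several places and any filters are not given in the sources used here, nor is whether counting used the strand of a read. Reads of near-identical genes, such as HSPA1A and HSPA1B, the histones and ribosomal proteins with pseudogenes, and reads of genes that overlap on opposite strands, may therefore be split or lost.

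The authors deposited a single table of RPKM values, a read count scaled by gene length and read total, for 19332 gene symbols in 11 libraries, and which reads make up the read total is not given in the sources used here. The table was used as deposited, and each column was assigned to a time and replicate number by its name. In 3246 of 3344 low genes (97.1%, with a tolerance of 0.02 reads) the values of a gene were whole multiples of a single step, as whole reads give, so that the relative depth of the libraries could be computed. With annotated transcript lengths, 705 of 2327 genes pointed to a common depth, 730 lengths lying within the window there and at most 57 in any other. The depth computed in this way ranged from 35700000 reads (8h replicate 2) to 54900000 (48h replicate 1), and was 44500000 for 0h replicate 1. No count test of changes between times was run, because the length of each gene that the authors used is not in the table.

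Libraries of the same time differed by more than counting noise, with a chi-square per degree of freedom of 5.76 to 67.5 over genes, and none was counted as a duplicate. The libraries are wells of a single culture split into 12 portions, so p-values measure the spread between wells. The 0, 8 and 24 h groups hold 3 libraries each and the 48 h group 2; no other library was analysed here.

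Genes with a mean of at least 0.5 RPKM over the 11 libraries were tested (12522 genes). A pseudocount of 0.5 was added and log2 taken, so log2 fold changes are on the log2(RPKM + 0.5) scale and understate the change of low genes. Linear models with a mean per time were fitted over all 11 libraries with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance prior, for 8, 24 and 48 h against 0 h, 24 h against 8 h and 48 h against 24 h. A moderated F test covered the 4 times. The difference between 48 and 8 h was tested in the same fit for genes and lists called in opposite directions at these times, its lists adjusted over 41 tests. P-values are two-sided and adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are called changed. Means ± SD are of the RPKM values, and SE is the standard error of the log2 fold change. On simulated data with the real means and spreads, a log2 change of 0.5 was recovered for 86%, 90%, 92%, 96% and 74% of 50 genes in these 5 comparisons and a change of 0.25 for 18%, 20%, 12%, 16% and 16%.

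Gene lists of pathways, complexes and cell type markers, 43 in all with 1055 distinct genes of which 1041 are in the table, were tested with limma's camera with the inter-gene correlation preset to 0.01. Lists needed 5 members after the filter, and p-values were adjusted over the 205 tests of 41 lists in 5 comparisons. Leukocyte markers, with 2 genes tested, and the mitochondrially encoded genes, none of whose 13 members is in the table, were left out. Members were counted as changed with p-values adjusted over all genes and, separately, adjusted over the list alone. Among genes past the F test the times of the highest and lowest mean were counted without a test. Overlaps of calls were set beside 100 simulations of unchanged groups and beside the product of the list sizes divided by the number of genes tested.

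The text names, for each comparison, the 5 largest rises and 5 largest falls among called genes with a mean of at least 1 RPKM and no overlap between the libraries of the 2 times, up to 4 members of each called list with the largest absolute changes, and, for comparisons with 0 h, genes from a panel of 40, leaving out some of the list and panel genes where these were many. Genes named outside this rule are said to be so. XIST and Y-linked genes were left out. The samples, tests, gene lists, naming rule and alternatives were chosen before the data were examined.

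The alternatives were pseudocounts of 0.1 and 1, no filter beyond a value above 0 in 1 library, a stricter filter of a mean of at least 2 RPKM, median-ratio scaling, quantile normalization, limma without the intensity trend or with its robust setting, fits of the 2 times compared alone, the replicate number as a term of the model, an estimated inter-gene correlation, and leaving out each library in turn. After the data were seen, fits without the 48 h libraries and with trends in transcript length, or in length, GC content and number of coding exons, removed from each library were added. Transcript lengths, GC content and exon numbers came from GENCODE release 29 for 12351 of the tested genes (98.6%). Of the table's symbols 16980 matched a current symbol, 1519 a synonym and 833 none. No coordinates are printed, because that annotation is of another build than the authors'. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the other steps.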

Results

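Human pulmonary microvascular endothelial cells, the primary cells that line the small vessels of the lung, were grown from a single culture split into 12 portions on 2 plates. They were then kept in 1% oxygen for 0, 8, 24 or 48 h. Gene expression was measured by RNA sequencing in 3 libraries each at 0, 8 and 24 h and in 2 libraries at 48 h, 11 libraries in all. The deposited values are RPKM, a read count scaled by gene length and read total, for 19332 genes, of which 12522 had a mean of at least 0.5 RPKM and were tested. Read totals are not given in the table, but the steps between its low values correspond to 35700000 reads in the shallowest library (8 h, replicate 2). In the deepest (48 h, replicate 1) they correspond to 54900000. Because the libraries come from wells of a single split culture, p-values here measure the spread between wells. No well was kept in normal oxygen for 8, 24 or 48 h among the libraries analysed here, so hours in hypoxia and hours in culture change together.

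Libraries of the same time resembled each other closely, with Pearson correlations across tested genes of 0.993 to 0.999, and the 48 h libraries stood apart. Correlations between a 0 h and an 8 h library were 0.961 to 0.994, and those between a 0 h and a 24 h library 0.963 to 0.978. A 48 h library correlated with a library of any other time at 0.815 to 0.859. The first principal component held 77.5% of the variance and separated the 48 h libraries from the other 9. The 48 h libraries also listed fewer genes at 0 (2452 and 2619, against 3480 to 3597 in the others) and a higher mean level of 383 olfactory receptor genes (0.0118 and 0.0103 RPKM, against 0.00384 to 0.00664).

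**Figure D1:**
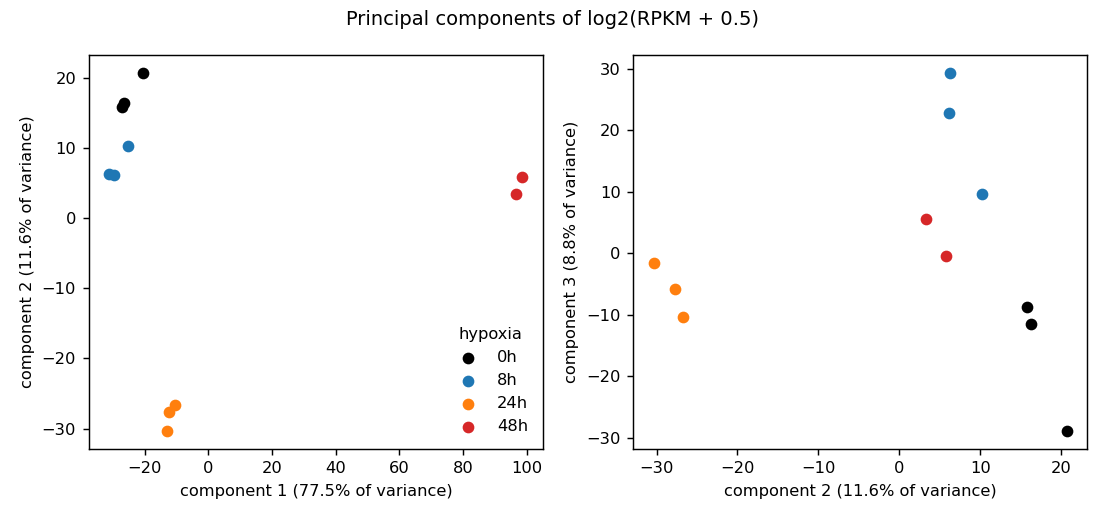
Scores of the 11 libraries (points, coloured by hours of hypoxia) on the first 3 principal components of log2(RPKM + 0.5), with the share of variance on each axis. The 48h libraries lie apart on component 1 (77.5% of variance), the 24h libraries on component 2 (11.6%), and component 3 (8.8%) spreads the 0h and 8h libraries.

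The question of the series is how the transcriptome changes in waves during extended hypoxia. The moderated F test over the 4 times found 12145 of 12522 genes changed at an adjusted p under 0.05. Among these, the mean level was highest at 0 h for 2725 genes, at 8 h for 4269, at 24 h for 1126 and at 48 h for 4025. It was lowest at 0 h for 1942 genes, at 8 h for 1497, at 24 h for 2667 and at 48 h for 6039. Among the 4998 genes whose highest and lowest means differed by at least 1 on the log2 scale, 1897 peaked at 48 h, 1643 at 8 h, 1011 at 0 h and 447 at 24 h. Of the same genes 2955 were lowest at 48 h. With median-ratio scaling of the libraries, 2825 genes peaked at 8 h and 1826 at 24 h, and 2705 were lowest at 8 h. This scaling moved the median log2 change of all genes from -0.11 to -0.01 at 24 h and from -0.19 to 0.01 at 48 h. Between 8 and 24 h it moved it from -0.16 to near 0, so the log2 changes below carry those shifts.

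At 8 h 14 of 41 gene lists passed the threshold with the preset correlation, 8 higher and 6 lower, and none with an estimated correlation (lowest adjusted p = 0.0955). The largest rises and falls of each comparison are given among genes with a mean of at least 1 RPKM and no overlap between the libraries of both times, and their order is that with a pseudocount of 0.5. CXCR4, a chemokine receptor, showed the largest rise, from 14.1 ± 1.17 to 60.9 ± 3.90 RPKM (SD, n = 3 each, adjusted p = 1.08e-08). Other large rises were those of INHBB, which encodes an activin subunit (log2 fold change 1.62, SE 0.10), NDUFA4L2, a mitochondrial protein induced by HIF (1.46, SE 0.13), and CYP26B1, a retinoic acid hydroxylase (1.42, SE 0.08). The angiogenic factor PGF went from 46.3 ± 5.61 to 123 ± 7.02 RPKM (SD, n = 3 each). The largest fall was that of IL6ST, the shared receptor subunit of the interleukin-6 family (68.6 ± 32.2 to 18.4 ± 13.5 RPKM, SD, n = 3 each). MGAT5 (-1.68, SE 0.25), RALGAPA2 (-1.55, SE 0.24), ZDHHC20 (-1.51, SE 0.23) and FAM171B (-1.48, SE 0.25) also showed large falls. In each of these 5 genes 0h replicate 2 was the highest 0 h library and 8h replicate 1 the highest 8 h library, which for IL6ST were at 106 and 34.0 RPKM. These 2 libraries also had the highest slope of log2 level on log2 transcript length of their times (0.161 and -0.061). In all, 4498 genes were higher and 2994 lower than at 0 h, of which 23 and 50 changed at least 2-fold. Without the 48 h libraries, an alternative added after the data were seen, the counts of higher and lower genes were 4397 and 2879.

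HIF target genes rose in 20 of 35 cases and fell in 5, also adjusted over the list alone (camera adjusted p = 0.0318, and adjusted p = 0.591 with an estimated correlation) at 8 h. CA9, a carbonic anhydrase, went from 0.389 ± 0.0267 to 1.28 ± 0.156 RPKM (SD, n = 3 each). ANKRD37 (0.88, SE 0.11), FAM162A (0.69, SE 0.11) and ADM, which encodes the vasodilator adrenomedullin (0.65, SE 0.12), were higher. VEGFA, at 17.6 ± 1.16 and 19.4 ± 0.303 RPKM (SD, n = 3 each), did not pass the threshold (log2 fold change 0.14, SE 0.07, adjusted p = 0.0997). Without 0h replicate 1 it did (adjusted p = 0.0425), as it did with a trend in transcript length removed (0.0403). The HIF target call was lost without 8h replicate 1 (adjusted p = 0.147) and without 0h replicate 3 (0.0571). Glycolytic genes rose in 15 of 19 cases and fell in 1, or 16 and 1 adjusted over the list alone (camera adjusted p = 0.000565, and adjusted p = 0.556 with an estimated correlation). Among them were ENO2 (0.75, SE 0.07), ALDOC (0.73, SE 0.08) and the lactate exporter SLC16A3 (0.73, SE 0.10). The HIF subunit transcript HIF1A went from 216 ± 25.6 to 129 ± 15.5 RPKM (SD, n = 3 each, adjusted p = 0.000176), and the log2 fold change of another, EPAS1, was -0.43, SE 0.09 (adjusted p = 0.00216). EGLN3, a prolyl hydroxylase that marks HIF for degradation, was higher (0.40, SE 0.08). Among endothelial panel genes, DLL4, a Notch ligand of tip cells (0.67, SE 0.06), and ANGPT2 (0.47, SE 0.07) were higher.

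Mitosis genes fell in 35 of 43 cases and rose in 1, or 36 and 1 adjusted over the list alone (camera adjusted p = 6.49e-16, and adjusted p = 0.0955 with an estimated correlation) at 8 h. MKI67, a marker of dividing cells, was lower (log2 fold change -1.22, SE 0.15), as were the spindle genes ASPM (-1.15, SE 0.13), CKAP2L (-1.08, SE 0.09), CDCA8 (-0.99, SE 0.07) and KIF23 (-0.98, SE 0.06). Sterol synthesis genes fell in 15 of 25 cases and rose in 3, or 15 and 4 adjusted over the list alone (camera adjusted p = 4.86e-05, and adjusted p = 0.169 with an estimated correlation). HMGCS1, an early enzyme of cholesterol synthesis, went from 44.2 ± 0.851 to 20.6 ± 0.529 RPKM (SD, n = 3 each). STARD4 (-0.99, SE 0.14) and SC4MOL (-0.94, SE 0.06) were lower. Fatty acid synthesis genes fell in 9 of 14 cases and rose in 1, also adjusted over the list alone (camera adjusted p = 0.000129, and adjusted p = 0.191 with an estimated correlation). They included FASN (-0.77, SE 0.14) and ACACA (-0.72, SE 0.10). NF-kB and inflammatory genes fell in 11 of 24 cases and rose in 5, or 12 and 5 adjusted over the list alone (camera adjusted p = 0.0274, and adjusted p = 0.249 with an estimated correlation), a call that the stricter filter ended (adjusted p = 0.0960). IL8 (-0.69, SE 0.08), CCL20 (-0.64, SE 0.09) and IL6 (-0.62, SE 0.08) were lower, whereas NFKBIA, the inhibitor of NF-kB, was higher (0.67, SE 0.08).

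Cytosolic ribosomal protein genes rose in 50 of 51 cases and fell in 0, also adjusted over the list alone (camera adjusted p = 2.59e-09, and adjusted p = 0.591 with an estimated correlation) at 8 h. Nuclear subunits of oxidative phosphorylation rose in 38 of 44 cases and fell in 1, or 39 and 1 adjusted over the list alone (camera adjusted p = 5.06e-06, and adjusted p = 0.598 with an estimated correlation). The medians of these lists were 0.57 and 0.48, with RPS21 (0.84, SE 0.17), RPS9 (0.79, SE 0.14), COX6B1 (0.73, SE 0.14) and NDUFA1 (0.71, SE 0.16) among them. Proteasome subunits rose in 20 of 31 cases and fell in 1, or 21 and 1 adjusted over the list alone (camera adjusted p = 0.00971, and adjusted p = 0.703 with an estimated correlation). PSMB3 (0.66, SE 0.13) and PSMA7 (0.63, SE 0.15) are examples. Epithelial markers rose in 6 of 7 cases and fell in 0, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.0276, and adjusted p = 0.464 with an estimated correlation). KRT7 was at 97.9 ± 10.6 and 128 ± 8.72 RPKM and KRT8 at 1.62 ± 0.247 and 2.45 ± 0.363 RPKM at 0 and 8 h (SD, n = 3 each). Across 12351 genes with an annotated transcript, the 8 h change fell with transcript length (Spearman rho = -0.587, genes not being independent replicates). With that trend removed from each library, an alternative added after the data were seen, the medians of ribosomal protein and oxidative phosphorylation genes were 0.27 and 0.20, with both calls kept. The proteasome call was lost with it (adjusted p = 0.597), as it was with trends in length, GC content and coding exon number removed (0.0614) and with quantile normalization (0.129). The epithelial call was lost in the same ways of trend removal (adjusted p = 0.135 and 0.359) and with the stricter filter (0.0606).

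Autophagy genes rose in 18 of 30 cases and fell in 0, also adjusted over the list alone (camera adjusted p = 0.00770, and adjusted p = 0.493 with an estimated correlation) at 8 h. MAP1LC3A (0.73, SE 0.12) and GABARAP (0.54, SE 0.11) belonged to these. p53 target genes rose in 11 of 23 cases and fell in 2, also adjusted over the list alone (camera adjusted p = 0.0434, and adjusted p = 0.564 with an estimated correlation). GDF15 (0.91, SE 0.11) and BBC3 (0.90, SE 0.13) were higher. This call was lost without 8h replicate 1 (adjusted p = 0.104), without 0h replicate 3 (0.103), with median-ratio scaling (0.0569) and with the replicate number as a block (0.0559). Ribosome biogenesis genes fell in 14 of 34 cases and rose in 5, also adjusted over the list alone (camera adjusted p = 0.0171, and adjusted p = 0.445 with an estimated correlation). POLR1A (-0.91, SE 0.15) and UTP20 (-0.71, SE 0.10) were lower, and the call was lost without 8h replicate 1 (adjusted p = 0.0786) and without 0h replicate 3 (0.0630). Oxygen-dependent dioxygenases fell in 8 of 25 cases and rose in 5, also adjusted over the list alone (camera adjusted p = 0.0466, and adjusted p = 0.591 with an estimated correlation). TET2, which oxidizes methylated cytosine, was lower (-0.60, SE 0.13). The dioxygenase call was lost without 0h replicate 2 (adjusted p = 0.119), 0h replicate 3 (0.0633), 8h replicate 2 (0.0804) or 8h replicate 3 (0.0737). It was also lost with the stricter filter (adjusted p = 0.0803), with the replicate block (0.0515) and with median-ratio scaling or quantile normalization (0.0569 and 0.0930), and turned to higher with the length trend removed (0.597). With median-ratio scaling 3666 genes were higher and 3774 lower than at 0 h, and with quantile normalization 3687 and 3584.

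At 24 h 23 of 41 gene lists passed the threshold with the preset correlation, 14 higher and 9 lower, and none with an estimated correlation (lowest adjusted p = 0.0899). NDUFA4L2 went from 4.45 ± 0.848 to 97.2 ± 8.98 RPKM (SD, n = 3 each, adjusted p = 5.09e-10). CA9 went from 0.389 ± 0.0267 to 11.1 ± 0.542 RPKM (SD, n = 3 each, adjusted p = 2.37e-11). Other large rises were those of IGFBP3, a binding protein for insulin-like growth factors (log2 fold change 3.29, SE 0.07), C5orf46 (2.82, SE 0.09) and HSD17B2, a steroid dehydrogenase (2.77, SE 0.07). CYP1A1, a target of the aryl hydrocarbon receptor, showed the largest fall with the pseudocount of 0.5 (6.86 ± 0.0995 to 0.0750 ± 0.0304 RPKM, SD, n = 3 each). Other large falls were those of IL1RL1, the receptor for interleukin-33 (-3.57, SE 0.08), which exceeded that of CYP1A1 with a pseudocount of 1, ELMOD1 (-3.39, SE 0.07), the chemokine CCL23 (-3.24, SE 0.15) and the Wnt antagonist DKK2 (-2.68, SE 0.09). In all, 2275 genes were higher and 4866 lower than at 0 h, of which 179 and 266 changed at least 2-fold. Without the 48 h libraries these counts were 2202 and 4750.

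HIF target genes rose in 22 of 35 cases and fell in 3, or 23 and 3 adjusted over the list alone (camera adjusted p = 3.91e-13, and adjusted p = 0.0955 with an estimated correlation) at 24 h. LOX, which cross-links collagen (1.92, SE 0.08), ANGPTL4 (1.70, SE 0.10) and TMEM45A (1.66, SE 0.09) were higher. VEGFA, the main vascular growth factor, went from 17.6 ± 1.16 to 53.5 ± 2.58 RPKM (SD, n = 3 each, adjusted p = 5.80e-09). Glycolytic genes rose in 16 of 19 cases and fell in 1, also adjusted over the list alone (camera adjusted p = 3.25e-09, and adjusted p = 0.249 with an estimated correlation). ALDOC (1.56, SE 0.08), ENO2 (1.55, SE 0.07), SLC16A3 (1.09, SE 0.10) and PGK1 (1.06, SE 0.07) were among them. HIF1A (-0.76, SE 0.09) and EPAS1 (-0.96, SE 0.09) transcripts were lower than at 0 h, and EGLN3 was higher (0.97, SE 0.08).

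Collagens and their modifying enzymes rose in 26 of 28 cases and fell in 1, or 27 and 1 adjusted over the list alone (camera adjusted p = 3.10e-18, and adjusted p = 0.0899 with an estimated correlation) at 24 h. COL1A1 went from 798 ± 33.4 to 2032 ± 72.1 RPKM (SD, n = 3 each), and the collagen prolyl hydroxylase P4HA2 was higher (1.58, SE 0.06). Fibroblast markers, which share COL1A1 and COL1A2 with that list, rose in 10 of 13 cases and fell in 1, or 10 and 2 adjusted over the list alone (camera adjusted p = 9.62e-07, and adjusted p = 0.0955 with an estimated correlation). THY1 (1.25, SE 0.07) and FAP (1.16, SE 0.07) were higher. Cell shares were not tested. Smooth muscle and pericyte markers rose in 7 of 12 cases and fell in 2, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.00763, and adjusted p = 0.187 with an estimated correlation). TAGLN was higher (1.52, SE 0.12) and RGS5 lower (-1.37, SE 0.08). TGF-beta and BMP response genes rose in 17 of 29 cases and fell in 8, also adjusted over the list alone (camera adjusted p = 0.000626, and adjusted p = 0.0899 with an estimated correlation). TGFBI was higher (1.96, SE 0.06). Basement membrane and matrix glycoproteins rose in 13 of 26 cases and fell in 4, also adjusted over the list alone (camera adjusted p = 2.33e-05, and adjusted p = 0.264 with an estimated correlation). FBLN5 was higher (1.58, SE 0.07) and POSTN went from 253 ± 13.2 to 74.0 ± 2.46 RPKM (SD, n = 3 each). Endoplasmic reticulum chaperones rose in 13 of 22 cases and fell in 1, also adjusted over the list alone (camera adjusted p = 8.96e-05, and adjusted p = 0.183 with an estimated correlation). They included HSPA5 (0.52, SE 0.06) and P4HB (0.51, SE 0.08). Epithelial markers rose in 5 of 7 cases and fell in 0, also adjusted over the list alone (camera adjusted p = 0.000420, and adjusted p = 0.216 with an estimated correlation). KRT19 was higher (1.16, SE 0.12).

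DNA replication genes fell in 42 of 42 cases and rose in 0, also adjusted over the list alone (camera adjusted p = 7.92e-16, and adjusted p = 0.0955 with an estimated correlation) at 24 h. Mitosis genes fell in 43 of 43 cases and rose in 0, also adjusted over the list alone (camera adjusted p = 7.92e-16, and adjusted p = 0.0955 with an estimated correlation). The replicative helicase subunits MCM4 (-1.34, SE 0.08) and MCM2 (-1.25, SE 0.08) and the mitotic regulators FOXM1 (-1.21, SE 0.07) and KIF20A (-1.21, SE 0.07) were lower. Homologous recombination and Fanconi genes fell in 26 of 28 cases and rose in 0, or 27 and 0 adjusted over the list alone (camera adjusted p = 7.38e-07, and adjusted p = 0.0899 with an estimated correlation). BRCA1 went from 9.26 ± 0.846 to 3.36 ± 0.243 RPKM (SD, n = 3 each). NRF2 target genes fell in 18 of 22 cases and rose in 0, or 19 and 0 adjusted over the list alone (camera adjusted p = 4.86e-05, and adjusted p = 0.264 with an estimated correlation). NQO1, a quinone reductase, went from 76.3 ± 8.31 to 17.8 ± 0.863 RPKM (SD, n = 3 each). SLC7A11, the cystine importer (-2.09, SE 0.09), TXNRD1 (-1.63, SE 0.07) and HMOX1 (-1.54, SE 0.08) were lower. Ribosome biogenesis genes fell in 25 of 34 cases and rose in 0, or 26 and 0 adjusted over the list alone (camera adjusted p = 0.000775, and adjusted p = 0.255 with an estimated correlation). POLR1A was lower (-0.94, SE 0.15). TCA cycle enzymes fell in 15 of 22 cases and rose in 1, or 16 and 1 adjusted over the list alone (camera adjusted p = 0.0156, and adjusted p = 0.591 with an estimated correlation). DLAT (-0.65, SE 0.06) and OGDH (-0.62, SE 0.08) were lower. Fatty acid synthesis genes fell in 10 of 14 cases and rose in 1, or 11 and 1 adjusted over the list alone (camera adjusted p = 0.0287, and adjusted p = 0.470 with an estimated correlation). ME1 was lower (-1.04, SE 0.06), and the call was lost with the length trend removed (adjusted p = 0.0651). Spliceosome genes fell in 20 of 37 cases and rose in 1, also adjusted over the list alone (camera adjusted p = 0.0306, and adjusted p = 0.591 with an estimated correlation). HNRNPM was lower (-0.63, SE 0.06), and the call was lost without 0h replicate 1 (adjusted p = 0.0619), without 0h replicate 3 (0.0507) and with median-ratio scaling (0.0627). Cytosolic ribosomal protein genes rose in 24 of 51 cases and fell in 0, or 21 and 0 adjusted over the list alone (camera adjusted p = 1.95e-08, and adjusted p = 0.591 with an estimated correlation). Quantile normalization ended that call (adjusted p = 0.197) and that of RPS6 (0.57, SE 0.11), which was 0.07 with that normalization (adjusted p = 0.376).

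Endothelial identity genes fell in 20 of 33 cases and rose in 5, also adjusted over the list alone (camera adjusted p = 0.0276, and adjusted p = 0.356 with an estimated correlation) at 24 h. This call was lost without 0h replicate 3 (adjusted p = 0.0563) and with the stricter filter (0.0522). NOS3, endothelial nitric oxide synthase, went from 14.6 ± 0.994 to 3.28 ± 0.152 RPKM, the lymphatic receptor LYVE1 from 49.1 ± 0.921 to 15.5 ± 0.970 RPKM, and VWF from 105 ± 10.1 to 195 ± 4.36 RPKM (SD, n = 3 each). Vasoactive and haemostatic genes rose in 13 of 32 cases and fell in 9, also adjusted over the list alone (camera adjusted p = 0.00549, and adjusted p = 0.286 with an estimated correlation), a call that quantile normalization ended (adjusted p = 0.206). The prostacyclin synthase PTGIS (2.71, SE 0.09), tissue factor F3 (1.87, SE 0.06) and the peptide APLN (1.70, SE 0.07) were higher. Angiogenic genes rose in 12 of 31 cases and fell in 11, also adjusted over the list alone (camera adjusted p = 0.0451, and adjusted p = 0.385 with an estimated correlation), with camera pointing to higher although their median was -0.003. That call was lost without 0h replicate 1 (adjusted p = 0.0716), 0h replicate 3 (0.0562), 8h replicate 1 (0.0517) or 24h replicate 1 (0.0609). It was also lost without a filter (adjusted p = 0.162), with the replicate block (0.0528) and with median-ratio scaling or quantile normalization (0.0829 and 0.116). Of the VEGF receptors, KDR was lower (-0.82, SE 0.13) and FLT1 higher (0.69, SE 0.09). NF-kB and inflammatory genes rose in 10 of 24 cases and fell in 6, also adjusted over the list alone (camera adjusted p = 0.0137, and adjusted p = 0.199 with an estimated correlation). CCL2 (2.06, SE 0.08), LIF (1.78, SE 0.08) and ICAM1 (1.01, SE 0.06) were higher. Immediate early genes rose in 11 of 27 cases and fell in 4, or 9 and 4 adjusted over the list alone (camera adjusted p = 0.00969, and adjusted p = 0.564 with an estimated correlation). CYR61 was higher (1.02, SE 0.07), and the call was lost with trends in transcript length, GC content and coding exon number removed (adjusted p = 0.122). With median-ratio scaling 3313 genes were higher and 3390 lower at 24 h, and with quantile normalization 3216 and 3340.

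**Figure D2:**
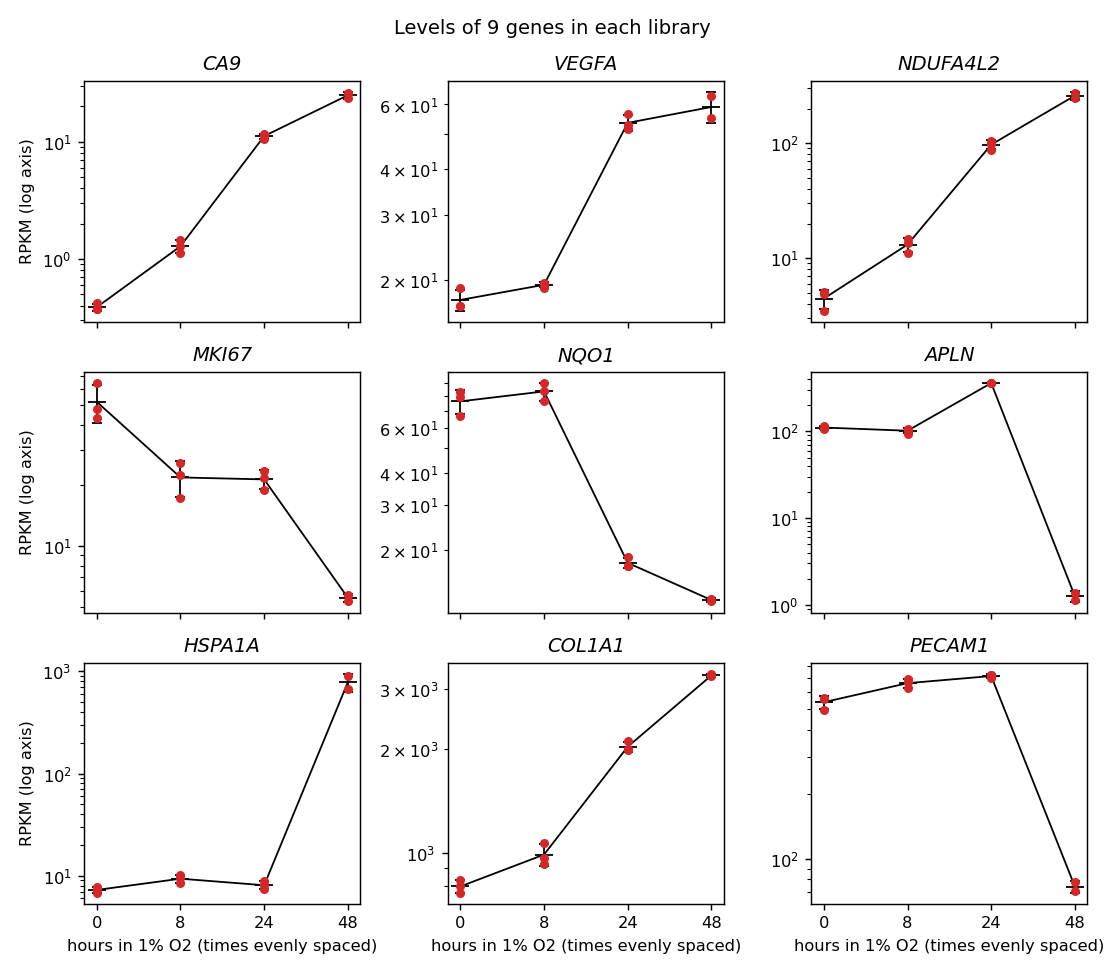
RPKM (log axis) of 9 genes against hours in 1% oxygen, drawn at even spacing: points are libraries, lines join the means and bars are SDs (n = 3, 2 at 48h). CA9 rises at each time, MKI67 is lower from 8h, NQO1 from 24h, APLN peaks at 24h, and HSPA1A and PECAM1 change mainly at 48h.

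At 48 h 23 of 41 gene lists passed the threshold with the preset correlation, 12 higher and 11 lower, and none with an estimated correlation (lowest adjusted p = 0.0899). HSPA1A, an inducible heat shock protein, went from 7.25 ± 0.461 (SD, n = 3) to 783 ± 159 RPKM (SD, n = 2), and its near-identical copy HSPA1B from 6.95 ± 0.742 (SD, n = 3) to 999 ± 80.9 RPKM (SD, n = 2). How reads shared by these copies were counted is not known. HSPA6 went from 0.00487 ± 0.00422 (SD, n = 3) to 105 ± 12.4 RPKM (SD, n = 2). NGFR, the low-affinity neurotrophin receptor, went from 0.0198 ± 0.00351 (SD, n = 3) to 84.8 ± 2.86 RPKM (SD, n = 2), and the chemokine CXCL3 was higher (log2 fold change 6.23, SE 0.12). The endothelial lectin CLEC14A showed the largest fall with pseudocounts of 0.5 and 1, from 144 ± 14.8 (SD, n = 3) to 1.24 ± 0.242 RPKM (SD, n = 2). Other large falls were those of TM4SF18 (-6.26, SE 0.08), the gap junction gene GJA5 (-6.20, SE 0.06), the largest with a pseudocount of 0.1, APLN (-6.00, SE 0.08) and GIMAP7 (-5.92, SE 0.15). In all, 4063 genes were higher and 6119 lower than at 0 h, of which 1466 and 2195 changed at least 2-fold. Log2 changes of genes near 0 at either time depend on the pseudocount, and the 48 h libraries correlated with those of other times at no more than 0.859.

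Heat shock genes rose in 19 of 20 cases and fell in 0, also adjusted over the list alone (camera adjusted p = 3.38e-09, and adjusted p = 0.119 with an estimated correlation) at 48 h. DNAJB1 (5.09, SE 0.07) and CRYAB (3.63, SE 0.12) were higher. Genes of the integrated stress response rose in 22 of 26 cases and fell in 2, also adjusted over the list alone (camera adjusted p = 2.17e-08, and adjusted p = 0.127 with an estimated correlation). DDIT3, which encodes the stress factor CHOP, went from 21.6 ± 4.35 (SD, n = 3) to 465 ± 60.1 RPKM (SD, n = 2). ATF3 (4.46, SE 0.09), PPP1R15A (4.13, SE 0.06) and TRIB3 (3.15, SE 0.07) were higher. Immediate early genes rose in 18 of 27 cases and fell in 7, also adjusted over the list alone (camera adjusted p = 0.000480, and adjusted p = 0.408 with an estimated correlation). KLF4 (5.84, SE 0.11), FOS (5.73, SE 0.09) and NR4A2 (5.07, SE 0.09) were higher. NF-kB and inflammatory genes rose in 18 of 24 cases and fell in 5, also adjusted over the list alone (camera adjusted p = 4.71e-05, and adjusted p = 0.0955 with an estimated correlation). TNFAIP3 (4.89, SE 0.10), BIRC3 (4.64, SE 0.09) and CXCL1 (3.71, SE 0.10) were higher. HIF target genes rose in 27 of 35 cases and fell in 4, also adjusted over the list alone (camera adjusted p = 7.38e-07, and adjusted p = 0.187 with an estimated correlation). CA9 reached 24.8 ± 1.64 RPKM and LOX 678 ± 19.1 RPKM (SD, n = 2 each). NDRG1 was higher (2.48, SE 0.06), whereas EGLN3 was lower (-1.92, SE 0.09). Glycolytic genes rose in 13 of 19 cases and fell in 4, also adjusted over the list alone (camera adjusted p = 0.00323, and adjusted p = 0.591 with an estimated correlation). ALDOC was higher (2.20, SE 0.09). Endoplasmic reticulum chaperones rose in 11 of 22 cases and fell in 3, also adjusted over the list alone (camera adjusted p = 0.0287, and adjusted p = 0.459 with an estimated correlation), a call lost without a filter (adjusted p = 0.116). DNAJB9 (1.14, SE 0.09) and XBP1 (1.02, SE 0.07) were higher. The cell cycle inhibitor CDKN1A went from 82.4 ± 5.95 (SD, n = 3) to 390 ± 39.9 RPKM (SD, n = 2). HIF1A was at 216 ± 25.6 (SD, n = 3) and 201 ± 5.57 RPKM (SD, n = 2), and did not pass the threshold (adjusted p = 0.405). The 48 h libraries correlated with other times at up to 0.859.

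Endothelial identity genes fell in 30 of 33 cases and rose in 3, also adjusted over the list alone (camera adjusted p = 3.38e-09, and adjusted p = 0.0899 with an estimated correlation) at 48 h, with a median of -3.05. The junction protein PECAM1 went from 540 ± 36.2 (SD, n = 3) to 74.1 ± 4.83 RPKM (SD, n = 2), and CDH5 was lower (-3.27, SE 0.10). CLDN5 (-5.02, SE 0.13), LYVE1 (-4.75, SE 0.06), SOX18 (-4.15, SE 0.09), the vasoconstrictor EDN1 (-4.06, SE 0.07), NOS3 (-3.47, SE 0.08) and VWF (-2.99, SE 0.09) were lower. The members that rose, chosen after their values were seen, were GATA2 (0.59, SE 0.07), JAM2 (0.45, SE 0.11) and PROX1 (0.55, SE 0.21). PROX1 was not called without 0h replicate 1 (adjusted p = 0.113), 0h replicate 3 (0.112) or 48h replicate 1 (0.253), without a filter (0.0582), with the 2 times alone (0.0538), with the replicate block (0.0761) or with the length trend removed (0.0567). FLT1 (0.80, SE 0.10) and DLL4 (0.58, SE 0.07), panel genes outside the list, were higher. Lymphatic endothelial markers fell in 7 of 9 cases and rose in 2, also adjusted over the list alone (camera adjusted p = 0.0400, and adjusted p = 0.199 with an estimated correlation). MMRN1 was lower (-4.01, SE 0.13), and the call was lost without 0h replicate 2 (adjusted p = 0.0759) and with trends in transcript length, GC content and coding exon number removed (0.0577). Fibroblast markers rose in 13 of 13 cases and fell in 0, also adjusted over the list alone (camera adjusted p = 7.44e-07, and adjusted p = 0.0955 with an estimated correlation), with a median of 1.63. COL1A2 (2.52, SE 0.07) and DCN (2.19, SE 0.07) were higher. Collagen genes rose in 26 of 28 cases and fell in 1, also adjusted over the list alone (camera adjusted p = 4.80e-11, and adjusted p = 0.127 with an estimated correlation). COL1A1 was at 3274 ± 31.9 RPKM (SD, n = 2). Smooth muscle and pericyte markers rose in 9 of 12 cases and fell in 2, also adjusted over the list alone (camera adjusted p = 0.00643, and adjusted p = 0.183 with an estimated correlation). PDGFRB went from 35.9 ± 1.89 (SD, n = 3) to 210 ± 2.01 RPKM (SD, n = 2), NOTCH3 was higher (1.97, SE 0.08) and RGS5 lower (-3.66, SE 0.08). TGF-beta and BMP response genes rose in 17 of 29 cases and fell in 10, also adjusted over the list alone (camera adjusted p = 0.0276, and adjusted p = 0.169 with an estimated correlation). BAMBI was higher (3.51, SE 0.10) and the receptor ACVRL1 lower (-3.38, SE 0.06). The TGF-beta call was lost without a filter (adjusted p = 0.156) and with median-ratio scaling or quantile normalization (0.0780 and 0.0819).

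Mitosis genes fell in 43 of 43 cases and rose in 0, also adjusted over the list alone (camera adjusted p = 3.16e-12, and adjusted p = 0.130 with an estimated correlation) at 48 h. ASPM (-3.28, SE 0.14) and DLGAP5 (-3.19, SE 0.08) were lower. DNA replication genes fell in 39 of 42 cases and rose in 1, also adjusted over the list alone (camera adjusted p = 1.25e-07, and adjusted p = 0.183 with an estimated correlation). FEN1 (-2.60, SE 0.09) and MCM3 (-2.46, SE 0.06) were lower. Homologous recombination and Fanconi genes fell in 23 of 28 cases and rose in 1, also adjusted over the list alone (camera adjusted p = 0.00288, and adjusted p = 0.130 with an estimated correlation). XRCC2 was lower (-2.21, SE 0.13). Spliceosome genes fell in 34 of 37 cases and rose in 2, also adjusted over the list alone (camera adjusted p = 1.75e-05, and adjusted p = 0.266 with an estimated correlation). The splicing factors SFRS5 (-2.54, SE 0.08) and SFRS2 (-2.40, SE 0.06) were lower, while the kinase CLK1 was higher (2.20, SE 0.06). Proteasome subunits fell in 30 of 31 cases and rose in 0, also adjusted over the list alone (camera adjusted p = 0.000282, and adjusted p = 0.591 with an estimated correlation). PSMA4 was lower (-1.43, SE 0.13). Oxidative phosphorylation subunits fell in 36 of 44 cases and rose in 0, also adjusted over the list alone (camera adjusted p = 0.00244, and adjusted p = 0.732 with an estimated correlation). NDUFB3 was lower (-1.69, SE 0.13). TCA cycle enzymes fell in 17 of 22 cases and rose in 2, also adjusted over the list alone (camera adjusted p = 0.0255, and adjusted p = 0.591 with an estimated correlation). SDHD was lower (-1.47, SE 0.12). Ribosome biogenesis genes fell in 31 of 34 cases and rose in 1, also adjusted over the list alone (camera adjusted p = 0.000120, and adjusted p = 0.198 with an estimated correlation). RRS1 was lower (-3.48, SE 0.10).

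Interferon-stimulated genes fell in 23 of 32 cases and rose in 7, also adjusted over the list alone (camera adjusted p = 0.0434, and adjusted p = 0.703 with an estimated correlation) at 48 h. IFI27 was lower (-3.47, SE 0.24). The interferon call was lost without 0h replicate 3 (adjusted p = 0.0630), without 48h replicate 2 (0.0523), with the stricter filter (0.0956) and with the length trend or all trends removed (0.0620 and 0.0915). Replication-dependent histones rose in 9 of 15 cases and fell in 2, also adjusted over the list alone (camera adjusted p = 0.0314, and adjusted p = 0.187 with an estimated correlation). HIST1H2BD, which has near-identical relatives, was higher (3.10, SE 0.16). The histone call was lost with median-ratio scaling or quantile normalization (adjusted p = 0.0615 and 0.0845), without a filter (0.0565) and with the stricter filter (0.316). With median-ratio scaling 5081 genes were higher and 5030 lower at 48 h, and with quantile normalization 4968 and 5188. Without a filter 6360 genes were higher.

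**Figure D3:**
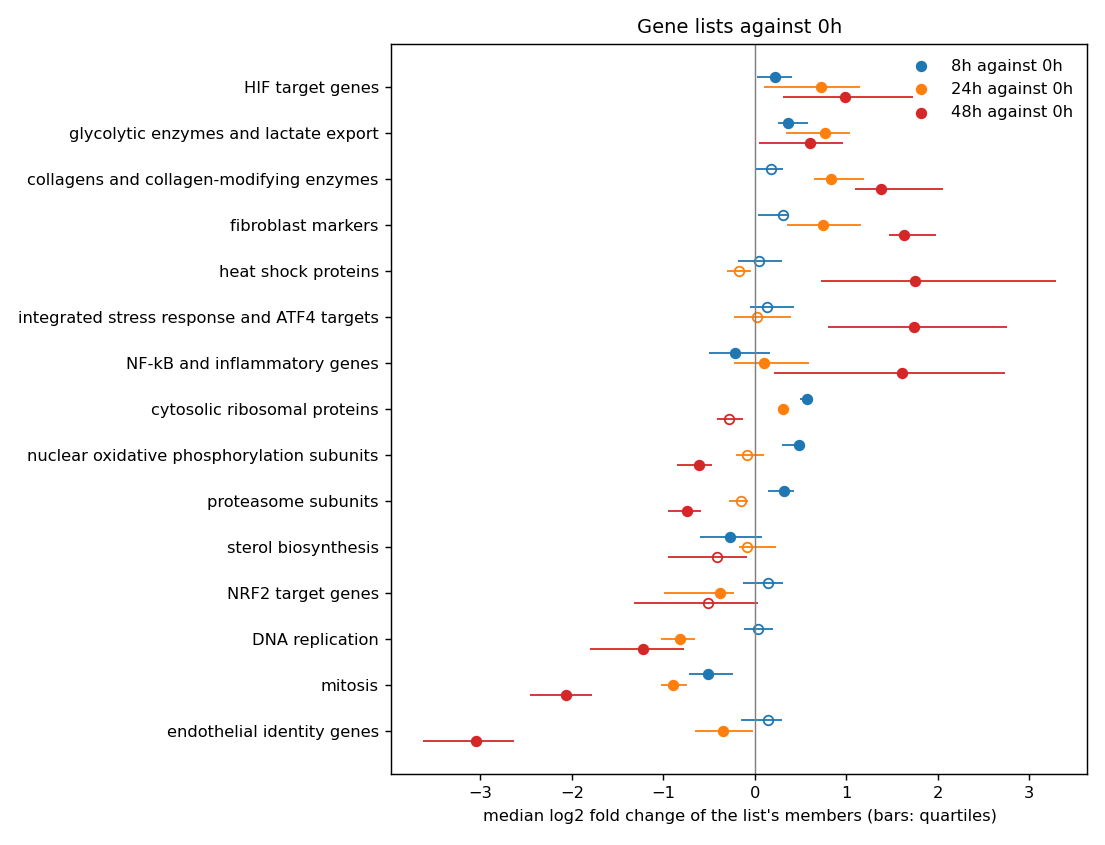
Median log2 fold change against 0h (points) of the members of 15 gene lists, with bars from the lower to the upper quartile, at 8h, 24h and 48h; filled points passed the camera threshold with the preset correlation and open points did not. HIF target, collagen and fibroblast lists lie further right at later times, and endothelial identity genes reach a median of -3.05 at 48h.

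Between 8 and 24 h 23 of 41 gene lists passed the threshold with the preset correlation, 13 higher and 10 lower, and none with an estimated correlation (lowest adjusted p = 0.0899). NDUFA4L2 showed the largest rise with pseudocounts of 0.5 and 1 (13.1 ± 1.90 to 97.2 ± 8.98 RPKM, SD, n = 3 each), and CA9 with a pseudocount of 0.1. The log2 fold changes of CA9 (2.71, SE 0.08), SYTL2 (2.44, SE 0.07), PTGIS (2.40, SE 0.09) and F3 (2.37, SE 0.06) were also large. CCL23 showed the largest fall (25.6 ± 3.53 to 1.03 ± 0.215 RPKM, SD, n = 3 each), and other large falls were those of IL1RL1 (-2.70, SE 0.08), ELMOD1 (-2.58, SE 0.07), METTL7A (-2.41, SE 0.09) and IGFBP1 (-2.35, SE 0.10). Sterol synthesis genes rose in 13 of 25 cases and fell in 6, also adjusted over the list alone (camera adjusted p = 5.06e-06, and adjusted p = 0.130 with an estimated correlation). HMGCS1 went from 20.6 ± 0.529 to 51.8 ± 1.60 RPKM (SD, n = 3 each), and SC4MOL (1.35, SE 0.06) and INSIG1 (1.22, SE 0.06) were higher. DNA replication genes fell in 42 of 42 cases and rose in 0, also adjusted over the list alone (camera adjusted p = 2.72e-15, and adjusted p = 0.0955 with an estimated correlation). TYMS (-1.30, SE 0.06) and E2F1 (-1.28, SE 0.09) were lower. Between 0 and 8 h these genes had risen in 12 of 42 cases and fallen in 10, or 11 and 10 adjusted over the list alone, with no list call (adjusted p = 0.980). HIF target genes rose in 23 of 35 cases and fell in 4, also adjusted over the list alone (camera adjusted p = 4.23e-13, and adjusted p = 0.0955 with an estimated correlation). VEGFA was higher (1.44, SE 0.07). NRF2 targets fell in 20 of 22 cases and rose in 0, also adjusted over the list alone (camera adjusted p = 8.19e-06, and adjusted p = 0.221 with an estimated correlation). NQO1 was lower (-2.20, SE 0.08). p53 targets fell in 17 of 23 cases and rose in 1, or 18 and 1 adjusted over the list alone (camera adjusted p = 0.00280, and adjusted p = 0.334 with an estimated correlation). GDF15 was lower (-1.53, SE 0.11).

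Collagen genes rose in 25 of 28 cases and fell in 1, also adjusted over the list alone (camera adjusted p = 4.22e-19, and adjusted p = 0.0899 with an estimated correlation) between 8 and 24 h. COL5A1 was higher (1.48, SE 0.08). Fibroblast markers rose in 9 of 13 cases and fell in 1, or 10 and 1 adjusted over the list alone (camera adjusted p = 4.37e-07, and adjusted p = 0.0955 with an estimated correlation). Matrix glycoproteins rose in 18 of 26 cases and fell in 2, or 19 and 2 adjusted over the list alone (camera adjusted p = 2.14e-10, and adjusted p = 0.130 with an estimated correlation). TGF-beta and BMP response genes rose in 14 of 29 cases and fell in 8, or 14 and 9 adjusted over the list alone (camera adjusted p = 0.000129, and adjusted p = 0.0899 with an estimated correlation). NF-kB and inflammatory genes rose in 13 of 24 cases and fell in 6, also adjusted over the list alone (camera adjusted p = 7.83e-06, and adjusted p = 0.0899 with an estimated correlation). Vasoactive genes rose in 13 of 32 cases and fell in 9, also adjusted over the list alone (camera adjusted p = 0.000282, and adjusted p = 0.187 with an estimated correlation). Glycolytic genes rose in 11 of 19 cases and fell in 1, also adjusted over the list alone (camera adjusted p = 4.15e-06, and adjusted p = 0.380 with an estimated correlation). Immediate early genes rose in 10 of 27 cases and fell in 4, also adjusted over the list alone (camera adjusted p = 0.000565, and adjusted p = 0.416 with an estimated correlation). Smooth muscle and pericyte markers rose in 6 of 12 cases and fell in 3, also adjusted over the list alone (camera adjusted p = 0.00969, and adjusted p = 0.187 with an estimated correlation). Endoplasmic reticulum chaperones rose in 7 of 22 cases and fell in 4, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.0319, and adjusted p = 0.464 with an estimated correlation). Epithelial markers rose in 4 of 7 cases and fell in 1, also adjusted over the list alone (camera adjusted p = 0.0378, and adjusted p = 0.493 with an estimated correlation).

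Among lower groups between 8 and 24 h, oxidative phosphorylation subunits fell in 42 of 44 cases and rose in 0, also adjusted over the list alone (camera adjusted p = 0.000238, and adjusted p = 0.682 with an estimated correlation). Proteasome subunits fell in 29 of 31 cases and rose in 0, also adjusted over the list alone (camera adjusted p = 0.000301, and adjusted p = 0.591 with an estimated correlation). Across genes the change from 8 to 24 h rose with transcript length (Spearman rho = 0.307), opposite to that from 0 to 8 h. With the length trend removed their medians went from -0.48 to -0.34 and from -0.49 to -0.35, with both calls kept (adjusted p = 0.000348 and 0.000289). TCA cycle enzymes fell in 18 of 22 cases and rose in 0, also adjusted over the list alone (camera adjusted p = 0.0122, and adjusted p = 0.591 with an estimated correlation). Mitosis genes fell in 33 of 43 cases and rose in 2, also adjusted over the list alone (camera adjusted p = 0.00116, and adjusted p = 0.465 with an estimated correlation). Interferon-stimulated genes fell in 25 of 32 cases and rose in 2, also adjusted over the list alone (camera adjusted p = 0.0243, and adjusted p = 0.663 with an estimated correlation). Recombination and Fanconi genes fell in 24 of 28 cases and rose in 0, or 25 and 0 adjusted over the list alone (camera adjusted p = 1.75e-05, and adjusted p = 0.0899 with an estimated correlation). Endothelial identity genes fell in 24 of 33 cases and rose in 2, or 25 and 2 adjusted over the list alone (camera adjusted p = 0.00982, and adjusted p = 0.271 with an estimated correlation). LYVE1 (-1.92, SE 0.06) and CLDN5 (-1.10, SE 0.12) were lower. The chaperone call was lost without 8h replicate 1 (adjusted p = 0.0529) and without a filter (0.0559). The epithelial call was lost without 8h replicate 1 (adjusted p = 0.184), without 24h replicate 3 (0.0671), with the stricter filter (0.0959) and with median-ratio scaling or quantile normalization (0.0872 and 0.0768). The interferon call was lost without 8h replicate 2 (adjusted p = 0.0574), with the stricter filter (0.0552) and with the length trend or all trends removed (0.0528 and 0.0614). In all, 1835 genes were higher and 5740 lower at 24 h than at 8 h, and 1785 and 5625 without the 48 h libraries. With median-ratio scaling these counts were 3310 and 3304, and with quantile normalization 3229 and 3488.

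Between 24 and 48 h 20 of 41 gene lists passed the threshold with the preset correlation, 9 higher and 11 lower, and none with an estimated correlation (lowest adjusted p = 0.0899). HSPA6 (log2 fold change 7.71, SE 0.08), NGFR (7.36, SE 0.08), HSPA1B (7.13, SE 0.12), HSPA1A (6.51, SE 0.12) and HSPA1L (6.26, SE 0.08), a neighbour of the HSPA1A and HSPA1B copies, showed large rises. HSPA6 and NGFR were near 0 at 24 h, so their order depends on the pseudocount, and with a pseudocount of 1 the rise of HSPA1B was the largest. APLN went from 362 ± 1.04 (SD, n = 3) to 1.25 ± 0.173 RPKM (SD, n = 2), and GJA5 (-7.14, SE 0.06), CLEC14A (-5.86, SE 0.11) and SULT1E1, an oestrogen sulfotransferase (-5.35, SE 0.07), were lower. ANKRD1, a target of mechanical signalling, went from 768 ± 19.1 (SD, n = 3) to 17.0 ± 0.292 RPKM (SD, n = 2). Endothelial identity genes fell in 29 of 33 cases and rose in 3, also adjusted over the list alone (camera adjusted p = 1.19e-09, and adjusted p = 0.0899 with an estimated correlation). CD34 was lower (-4.26, SE 0.07). Angiogenic genes fell in 19 of 31 cases and rose in 5, also adjusted over the list alone (camera adjusted p = 0.00556, and adjusted p = 0.216 with an estimated correlation). PDGFB was lower (-3.63, SE 0.07). Vasoactive genes fell in 18 of 32 cases and rose in 7, or 18 and 8 adjusted over the list alone (camera adjusted p = 0.0135, and adjusted p = 0.356 with an estimated correlation). EDN1 was lower (-4.67, SE 0.07). HIF target genes rose in 18 of 35 cases and fell in 5, or 17 and 5 adjusted over the list alone (camera adjusted p = 0.0144, and adjusted p = 0.556 with an estimated correlation), a call lost without a filter (adjusted p = 0.0634). DDIT4 (1.82, SE 0.12) and BHLHE40 (1.64, SE 0.09) were higher, while EGLN3 went from 17.6 ± 0.519 (SD, n = 3) to 1.93 ± 0.0667 RPKM (SD, n = 2). p53 targets rose in 14 of 23 cases and fell in 7, or 15 and 7 adjusted over the list alone (camera adjusted p = 0.0255, and adjusted p = 0.494 with an estimated correlation), a call lost without a filter (adjusted p = 0.0979). GDF15 (3.06, SE 0.12) and SESN2 (3.04, SE 0.06) were higher. The 48 h libraries correlated with those of 24 h at 0.849 to 0.859.

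Heat shock genes rose in 20 of 20 cases and fell in 0, also adjusted over the list alone (camera adjusted p = 9.95e-10, and adjusted p = 0.106 with an estimated correlation) between 24 and 48 h. Integrated stress response genes rose in 23 of 26 cases and fell in 3, also adjusted over the list alone (camera adjusted p = 1.14e-07, and adjusted p = 0.130 with an estimated correlation). NF-kB and inflammatory genes rose in 17 of 24 cases and fell in 5, also adjusted over the list alone (camera adjusted p = 0.000309, and adjusted p = 0.106 with an estimated correlation). SELE, an adhesion molecule of activated endothelium, was higher (3.87, SE 0.08). Immediate early genes rose in 17 of 27 cases and fell in 8, also adjusted over the list alone (camera adjusted p = 0.00502, and adjusted p = 0.527 with an estimated correlation). Collagens rose in 24 of 28 cases and fell in 0, also adjusted over the list alone (camera adjusted p = 9.54e-06, and adjusted p = 0.249 with an estimated correlation). Fibroblast markers rose in 12 of 13 cases and fell in 0, also adjusted over the list alone (camera adjusted p = 0.000192, and adjusted p = 0.169 with an estimated correlation). DDR2 (2.53, SE 0.20) and PDGFRA (1.76, SE 0.08) were higher. Replication-dependent histones rose in 8 of 15 cases and fell in 2, also adjusted over the list alone (camera adjusted p = 0.0451, and adjusted p = 0.199 with an estimated correlation). The histone call was lost without 0h replicate 2 (adjusted p = 0.0501), without 48h replicate 2 (0.0514), with median-ratio scaling or quantile normalization (0.0633 and 0.0845) and with the stricter filter (0.505).

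Among lower groups between 24 and 48 h, mitosis genes fell in 42 of 43 cases and rose in 0, or 42 and 1 adjusted over the list alone (camera adjusted p = 5.58e-10, and adjusted p = 0.169 with an estimated correlation). BUB1B was lower (-2.15, SE 0.10). Spliceosome genes fell in 32 of 37 cases and rose in 3, also adjusted over the list alone (camera adjusted p = 3.58e-05, and adjusted p = 0.286 with an estimated correlation). SFRS5 was lower (-2.80, SE 0.08) and CLK1 higher (2.28, SE 0.06). Oxidative phosphorylation subunits fell in 39 of 44 cases and rose in 0, also adjusted over the list alone (camera adjusted p = 0.000508, and adjusted p = 0.703 with an estimated correlation). UQCRFS1 was lower (-1.45, SE 0.09). Cytosolic ribosomal proteins fell in 45 of 51 cases and rose in 0, also adjusted over the list alone (camera adjusted p = 0.000656, and adjusted p = 0.741 with an estimated correlation). RPS6 was lower (-0.94, SE 0.13). The change from 24 to 48 h also rose with transcript length (Spearman rho = 0.231), and with that trend removed the oxidative phosphorylation and ribosomal protein medians went from -0.54 to -0.32 and from -0.61 to -0.36, with both calls kept (adjusted p = 0.00441 and 0.00335). DNA replication genes fell in 30 of 42 cases and rose in 7, also adjusted over the list alone (camera adjusted p = 0.0172, and adjusted p = 0.564 with an estimated correlation). Lymphatic markers fell in 7 of 9 cases and rose in 2, also adjusted over the list alone (camera adjusted p = 0.0287, and adjusted p = 0.187 with an estimated correlation). Proteasome subunits fell in 30 of 31 cases and rose in 0, or 31 and 0 adjusted over the list alone (camera adjusted p = 0.000327, and adjusted p = 0.591 with an estimated correlation). Ribosome biogenesis genes fell in 25 of 34 cases and rose in 4, or 26 and 4 adjusted over the list alone (camera adjusted p = 0.00491, and adjusted p = 0.334 with an estimated correlation). In all, 4465 genes were higher and 5535 lower at 48 h than at 24 h, of which 1441 and 1667 changed at least 2-fold. With median-ratio scaling 5045 were higher and 4991 lower, and with quantile normalization 4912 and 5051. Without a filter 6777 were higher.

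Calls against 0 h overlapped between times. Of the genes tested, 1384 were higher at both 8 and 24 h and 2039 lower at both, or 1317 and 1935 without the 48 h libraries. At both 8 and 48 h 1508 were higher and 1592 lower, and at both 24 and 48 h 1257 and 3066. Independent lists of these sizes would share 817 and 1163 genes for 8 and 24 h, 1459 and 1463 for 8 and 48 h, and 738 and 2378 for 24 and 48 h. With median-ratio scaling the higher and lower genes shared were 1696 and 1855 for 8 and 24 h, 1572 and 1675 for 8 and 48 h, and 1906 and 2008 for 24 and 48 h, and with quantile normalization 1627 and 1749, 1554 and 1637, and 1911 and 2091. Simulated unchanged groups against the same 0 h libraries shared 0 genes in each of 100 simulations. With at most 3 calls in a comparison they give no value for such lists. All 3 comparisons share 3 libraries at 0 h, too few to split, so part of any excess may come from these. Of the 43 gene lists fixed beforehand 41 could be tested. With the estimated correlation, lists with an unadjusted p under 0.05 numbered 3, 10 and 15 at 8, 24 and 48 h against 0 h, 11 at 24 h against 8 h and 8 at 48 h against 24 h.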

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

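The tests of transcript length, of marker spread, of correlation between libraries, of exon number and of olfactory receptor genes were chosen only after the result was seen. Genes and gene lists are given first that passed the threshold against 0 h in opposite directions at 2 times, with the difference between these times tested by limma or camera. With 2 or 3 libraries in each group, single libraries were not tested for standing apart.

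From 8 to 24 h, ANGPT2 went from higher to lower than at 0 h (log2 difference -0.79, SE 0.07, adjusted p = 3.23e-06). HMGCS1 (1.31, SE 0.05) and COL4A1 (1.08, SE 0.08) went from lower to higher. As a list, NF-kB and inflammatory genes did so (median difference 0.28, adjusted p = 7.83e-06, and adjusted p = 0.0899 with an estimated correlation). Their call at 8 h was lost with the stricter filter (adjusted p = 0.0960). COL4A1 lost its call at 8 h without 0h replicate 2 (adjusted p = 0.0666), 8h replicate 2 (0.0864) or 8h replicate 3 (0.0620), with the 2 times alone (0.0658) or with the length trend removed (0.788). ANGPT2 lost its call at 24 h with trends in length, GC content and coding exon number removed (adjusted p = 0.0530).

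From 8 to 48 h, EGLN2 (-1.79, SE 0.10), EGLN3 (-2.32, SE 0.09), ANGPT2 (-3.53, SE 0.08) and PECAM1 (-3.15, SE 0.08) went from higher to lower. SLC2A3 (1.32, SE 0.07) and COL4A1 (1.29, SE 0.09) went from lower to higher. Oxidative phosphorylation subunits (-1.03, adjusted p = 1.53e-05, and 0.620 with an estimated correlation) and proteasome subunits (-1.08, adjusted p = 3.11e-05, and 0.566 with an estimated correlation) went from higher to lower as lists. NF-kB and inflammatory genes went from lower to higher (1.69, adjusted p = 1.04e-06, and 0.0757 with an estimated correlation). The proteasome call at 8 h was lost with quantile normalization (adjusted p = 0.129) and with the length trend or all trends removed (0.597 and 0.0614), and that of NF-kB genes with the stricter filter (0.0960). PECAM1 was not higher at 8 h with quantile normalization (-0.14, adjusted p = 0.0733). SLC2A3 lost its call at 8 h without 8h replicate 3 (adjusted p = 0.0619) and with the length trend or all trends removed (0.0557 and 0.159), and EGLN2 with all trends removed (0.0823).

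From 24 to 48 h, HIF3A (-1.29, SE 0.09), EGLN3 (-2.89, SE 0.09), EDN1 (-4.67, SE 0.07), APLN (-7.70, SE 0.08), PECAM1 (-3.27, SE 0.08), VWF (-3.88, SE 0.09) and HMGCS1 (-1.41, SE 0.06) went from higher to lower. ARNT went from lower to higher (0.53, SE 0.09, adjusted p = 0.000128). The call of ARNT at 24 h was lost without 0h replicate 2 (adjusted p = 0.146), 8h replicate 3 (0.0570), 24h replicate 1 (0.0729), 24h replicate 2 (0.0585), 24h replicate 3 (0.147), 48h replicate 1 (0.0557) or 48h replicate 2 (0.0557). It was also lost with median-ratio scaling (adjusted p = 0.344), quantile normalization (0.479), no filter (0.0644) and the replicate block (0.0575). PECAM1 was not called at 24 h with quantile normalization (0.05, adjusted p = 0.559).

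At 8 h shorter transcripts were higher and longer ones lower than at 0 h. With the trend removed 11 of 14 lists kept call and direction. Medians went from 0.57 to 0.27 (ribosomal proteins) and 0.48 to 0.20 (oxidative phosphorylation subunits). Length bias as the whole cause stays open, since the authors' gene lengths are unknown. Proteasome subunits (0.32 and 0.10, interquartile range 0.29 and 0.21), epithelial markers (0.44 and 0.19, interquartile range 0.11 and 0.18) and dioxygenases (-0.15 and 0.08, interquartile range 0.21 and 0.23) lost their calls as their medians moved towards 0 or past it. For the trend itself, a length bias of RNA or library quality may be the cause, because the slope of log2 level on log2 length differed between 0 h libraries by up to 0.158, or 77.9% of the difference between the mean slopes of 8 and 0 h (-0.203). An effect of hypoxia on transcripts of different length stays open and was not tested.

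At 48 h endothelial identity genes were lower and fibroblast markers higher than at 24 h. The SD of the log2 changes of 13 fibroblast markers (0.68) was 8.15 times their median standard error. A lower share of endothelial cells need not raise them alike and stays open, also at 24 h, as does a change within cells. COL1A1 was at 798 ± 33.4 RPKM (SD, n = 3) already at 0 h. Another culture, batch or label of the 48 h libraries cannot be told apart from 48 h of hypoxia. Both libraries correlated with other times at up to 0.859, and no other time shares this. The effect of 48 h of hypoxia stays open and could not be tested apart.

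Genes with 1 coding exon were lower at 48 h than at 24 h (median -0.59, SE 0.0488, 599 genes), and genes with over 20 were higher (0.16, SE 0.0189, 1591 genes). A background of genomic DNA or silent genes at 48 h is argued against as the cause, because the olfactory receptor mean rose so little from the lowest 24 h to the highest 48 h library that it would shift a gene at 0.5 RPKM by a log2 of only 0.00991, and upwards. Loss of exon junction reads stays open. The change followed junctions per kilobase (Spearman rho = 0.0518 across genes) less than coding exon number (0.213), unadjusted for length. A batch of library preparation or counting cannot be told apart from time, because all 48 h libraries differ from those of 24 h in the contrast between both classes (-0.772, against a largest range within a time of 0.209). Few exons were not told apart from short transcripts (rho = 0.231 with length). An effect of 48 h of hypoxia stays open and was not tested.

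Of 100 regroupings of the libraries, only the real one gave 12145 genes in the F test over the 4 times (highest other 6958). Chance is thus unlikely for the times together. For 3 against 3 libraries, 10 splits are too few for a share under 0.05. The real splits gave 7492 genes at 8 h, 7141 at 24 h and 7575 between 8 and 24 h, the highest other split gave 0 in each case, and 1 split gave as many. Gene lists past the threshold numbered 14, 23 and 23 in the real splits and 16, 25 and 20 in the highest others, and 3, 3 and 1 splits gave as many.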

How the results depend on the processing

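Fits without the 48 h libraries and with trends removed were chosen only after the result was seen. Many genes were named for large changes and say little about smaller ones. Of 250 results of named genes, 242 kept direction and side of the threshold under each computable alternative fixed beforehand. Of 103 list calls 80 did so apart from the estimated correlation, 23 were ended by at least 1, and 13 by leaving out a library. With the estimated correlation 0 lists passed in each of the 5 comparisons. Without a filter, which tests more genes, 6360 genes were higher at 48 h than at 0 h and 6777 than at 24 h, 3035 were lowest at 0 h and 6291 highest at 48 h. With median-ratio scaling, which centres the changes of all genes, 3310 genes were higher and 3304 lower at 24 h than at 8 h. It gave 2825 genes highest and 2705 lowest at 8 h, 1826 highest at 24 h, and 1906 higher and 2008 lower at both 24 and 48 h. With quantile normalization 3229 and 3488 genes were higher and lower at 24 h than at 8 h, 2608 lowest at 8 h, 1755 highest at 24 h and 1911 higher at both 24 and 48 h. PECAM1 at 8 h turned to -0.14 with it. At 8 h the dioxygenase list turned to higher with the length trend (adjusted p = 0.597) or all trends removed (0.718). So did COL4A1 with all removed (log2 fold change 0.041). The causes were not tested. Leaving out 1 library moved no count of genes or lists past 1.5 times. Genes higher at 8 h ranged from 3558 to 4708, at 24 h from 1822 to 2407 and at 48 h from 3700 to 4153, and genes lower from 2306 to 3302, 4145 to 5090 and 5626 to 6287. Without a 48 h library, the other is assumed to vary like the other groups. With the replicate number as a block, 4349 genes were higher and 2887 lower at 8 h, 2198 and 4714 at 24 h, and 3991 and 5992 at 48 h. The block ended the list calls of p53 targets (0.0559) and dioxygenases (0.0515) at 8 h and of angiogenic genes at 24 h (0.0528), and the gene calls of ARNT at 24 h and PROX1 at 48 h. The numbers do not pair the libraries, since correlations of deviations were -0.653 to 0.603 for the same number (6 of 15 above 0.1) and -0.594 to 0.75 for different ones. A log2 change of 0.25 was recovered in 12% to 20% of simulated genes. Far fewer genes changed there than in the data, so this is no limit here. The spread between libraries of a time was 5.76 to 67.5 times counting noise (chi-square per degree of freedom).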

Other observations

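No test in this part was chosen only after the result was seen, but the 3 genes of the last paragraph were. Of the 41 gene lists tested, 7 passed in no comparison. Notch pathway genes rose in 11 of 20 cases and fell in 4, or 12 and 4 adjusted over the list alone (no call, camera adjusted p = 0.0959, and adjusted p = 0.459 with an estimated correlation) at 8 h. At 48 h they rose in 12 of 20 cases and fell in 7, also adjusted over the list alone (no call, camera adjusted p = 0.267, and adjusted p = 0.591 with an estimated correlation). Iron uptake and storage genes fell in 8 of 14 cases and rose in 1, also adjusted over the list alone (no call, camera adjusted p = 0.106, and adjusted p = 0.286 with an estimated correlation) at 24 h. Matrix metalloproteinases and their inhibitors fell in 11 of 19 cases and rose in 7, also adjusted over the list alone (no call, camera adjusted p = 0.857, and adjusted p = 0.951 with an estimated correlation) at 24 h, with a median of -0.39 although the test pointed to higher. HIF pathway components, the sensors and subunits of the oxygen-regulated factors, fell in 10 of 16 cases and rose in 4, also adjusted over the list alone (no call, camera adjusted p = 0.360, and adjusted p = 0.614 with an estimated correlation) at 48 h. Aminoacyl-tRNA synthetases fell in 11 of 20 cases and rose in 2, also adjusted over the list alone (no call, camera adjusted p = 0.255, and adjusted p = 0.744 with an estimated correlation) at 24 h. Metallothioneins and zinc response genes fell in 4 of 9 cases and rose in 3, also adjusted over the list alone (no call, camera adjusted p = 0.941, and adjusted p = 0.955 with an estimated correlation) at 48 h, again with a negative median (-0.06) and a test direction of higher. Apoptosis regulators fell in 12 of 28 cases and rose in 9, also adjusted over the list alone (no call, camera adjusted p = 0.766, and adjusted p = 0.827 with an estimated correlation) at 48 h, the median being -0.08 and the direction of the test higher.

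EGLN3, CA9 and APLN, all measured as HIF-related or endothelial genes, took different courses over the 4 times. EGLN3 was at 8.77 ± 1.19, 11.7 ± 0.0758 and 17.6 ± 0.519 RPKM at 0, 8 and 24 h (SD, n = 3 each) and at 1.93 ± 0.0667 RPKM at 48 h (SD, n = 2). CA9 was at 0.389 ± 0.0267, 1.28 ± 0.156 and 11.1 ± 0.542 RPKM at 0, 8 and 24 h (SD, n = 3 each) and at 24.8 ± 1.64 RPKM at 48 h (SD, n = 2). APLN was at 111 ± 4.38, 102 ± 6.45 and 362 ± 1.04 RPKM at 0, 8 and 24 h (SD, n = 3 each) and at 1.25 ± 0.173 RPKM at 48 h (SD, n = 2).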
